A study of Mus musculus with 30 samples.

How the data were processed

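The series measured antibody heavy-chain (Igh) V(D)J recombination in mouse cells by HTGTS-V(D)J-seq, which amplifies genomic DNA outward from a bait primer at the JH4 segment and reads the sequence joined to it. There were 30 libraries in 10 groups of 3. The 18 bone marrow libraries came from sorted B220+ IgM− CD43+ pro-B cells of 129SV mice with 6 genotypes of IGCR1, the intergenic control region 1 that lies between the V and D segments and carries a pair of CTCF-binding elements (CBE1 and CBE2): WT, CBE1 mutated (CBE1mut), CBE2 mutated (CBE2mut), both mutated (CBE12mut), CBE1 inverted (CBE1inv) and CBE2 inverted (CBE2inv). The 12 v-Abl libraries came from a C57BL/6 RAG1-deficient, Emu-Bcl2, v-Abl-transformed pro-B line with a single Igh allele and a degron on WAPL, the factor that unloads cohesin. Its parent line (WT) and a line without the CBE array at the 3' end of the locus (3CBEdel) were each kept untreated or treated with auxin (IAA, 150 µM) and doxycycline (2 µg/mL) for 3 days. The v-Abl cells received RAG by retrovirus and were arrested with STI-571 (3 µM) for 4 days.

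The deposited files hold no abundance value of another kind: per the file headers, each line is 1 read with a bait-to-prey junction, and its columns give positions and orientations on the alignment target and in the read. Per the labels, bone marrow reads were aligned to a target that joins a 129 Igh sequence with mm9 and v-Abl reads to mm9, with Bowtie2 (version not stated), and an enzyme blocking step was left out. The deposited files have a duplicate column that is 0 on every line, although read sequences repeat. Levels were made here by tabulating junctions.

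Each junction was assigned to a V or D segment when it lay within the segment or within 100 bp of it. Segment positions in mm9 came from the annotation of that build. In bone marrow, positions came from clusters of at least 50 joins, matched by sequence with BLAST 2.17.0 to the C57BL/6 segments and named at 97% identity or more with a clear closest match, or 99% between named neighbours. The mm9 part of the bone marrow target was found to be shifted by 390222 bp. This gave 142 V and 26 D segments in bone marrow and 123 V and 21 D segments in v-Abl cells. Of the bone marrow segments, 74 could be named by neither route and are given by position, as are 2 of the v-Abl segments. Bone marrow coordinates refer to the deposited alignment target and are not comparable with mm9. Related V segments can share sequence, so the deposited alignment decided which member received a read.

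The V share is the percentage of V joins among V plus D joins of a library. Group means were compared by exact two-sided permutation tests over 20 relabelings, for which the smallest p that 3 against 3 libraries allow is 0.1, by a permutation test of the variance between the 6 bone marrow genotypes with 100000 draws, and by an exact test with treatment permuted within v-Abl genotype. The difference between the treatment effects of both v-Abl genotypes was tested with genotype permuted within treatment. Segments with at least 10 junctions in at least 3 libraries (160 in bone marrow, 78 in v-Abl cells, where 43 of 66 V segments passed only with treated libraries) were fitted with limma 3.58.1 voom in R 4.3.3, with all junctions of a library as its size and no block. Bone marrow and v-Abl libraries were fitted apart, each with 1 shared estimate of the spread. The 11 zones of the locus (JH, downstream of JH, beyond the 3' end, first, middle and last D, the interval from D to V, V segments in 3 parts of equal length by distance from D, and the rest of the genome) were fitted with limma on log2(junctions per 100000 + 1). All adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05. The 11 segment lists (all D, the 10 V nearest to D that carry joins, the Ighv5, Ighv2, Ighv1 and Ighv8 families, the other V families together, the 3 V parts, and V pseudogenes) were tested with camera from limma, at a preset correlation of 0.01 and with an estimated correlation.

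The rule for naming segments, the groups, tests, lists and most alternatives were set before the data were examined. Fixed for every contrast were Ighd4-1, the D nearest to JH, Ighd1-1, the D farthest from it in the main D group, and Ighv5-2, Ighv2-2 and Ighv5-4 near the D end of the V segments. Open to naming as well were up to 10 risers and 10 fallers with the largest log2 change among called segments whose 3 libraries of each group did not overlap and whose mean reached 20 junctions per 100000 in 1 of the groups. Not all of these are given in the text. Ighv2-3 and Ighv5-6 in the contrasts given below met this rule.

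Values read from the read sequences were computed afterwards: the D segment inside V joins (a run of at least 8 bases that matches 1 D), the reading frame of V joins (also without the 4 segments Ighv5-1, Ighv5-2, Ighv2-2 and Ighv5-4), the orientation and D content of joins between JH4 and other JH segments, and the position of joins between D and V. Junctions with other JH segments per 100 D joins were computed afterwards as well. The reading frame was taken from the conserved cysteine of V to the conserved tryptophan of JH4. The longest stretch of unaligned bases between bait and prey in the deposited reads was 30 bases.

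The fits were tested on simulated counts drawn from the real means. In 10 draws for CBE12mut against WT, with 40 of 160 segments changed in each, 56.5% of segments changed 2-fold and 99% of those changed 4-fold were called, with 1.09% of unchanged segments called. In 10 draws for treated against untreated WT v-Abl cells, with 8 of 78 segments changed in each, the shares were 17.5%, 57.5% and 3.27%. As many segments were made to rise as to fall. A shift of most segments in the same direction, as in the real contrasts, was not simulated. The shares of unchanged segments called do not cover such a shift.

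Libraries held 11105 to 98682 junctions in bone marrow and 13180 to 175957 in v-Abl cells. The widest 95% Wilson interval of a library's V share was ± 0.962 percentage points in bone marrow and ± 0.450 in v-Abl cells. Reads were made by PCR and are not independent molecules, so these intervals cover counting error only. Between replicates, chi-square over degrees of freedom across segments was 3.46 to 49.1 in 30 pairs of libraries. The labels do not say whether replicates are separate animals, clones or infections, so every p-value measures the spread between samples.

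Per the file names, the WT, CBE12mut, CBE1mut and CBE1inv libraries share a sequencing run, and the CBE2mut and CBE2inv libraries share another. In v-Abl cells, replicate 1 of WT and replicate 3 of 3CBEdel were each in a run of their own, and the other 8 libraries shared a run.

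The alternatives collapsed reads with the same coordinates or the same sequence, kept only the orientation of deletional joining, scaled to V plus D joins or by the median of ratios, removed the filter, used limma trend on log2 values, fitted only the 2 groups compared, used the replicate number or the run as a block, kept only the run that most v-Abl libraries share or only the run that holds bone marrow WT, used a pseudocount of 0.5, assigned junctions within 20 bp, and left out each library in turn. The 20 bp setting was not run for zones, whose bounds do not use it. Collapsing identical read sequences and keeping only the run that holds WT were chosen after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.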

Results

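HTGTS-V(D)J-seq libraries from a JH4 bait were made from 18 bone marrow pro-B samples with 6 IGCR1 genotypes and from 12 v-Abl pro-B samples with 2 genotypes and 2 treatments, 3 libraries per group. A D join marks DJH rearrangement, the first step of heavy-chain assembly, and a V join marks a completed VDJH rearrangement. The 18 bone marrow libraries held 1139295 junctions, and V plus D joins were 82.4% to 97.8% of each library. Depth was 57970 to 89905 junctions in WT, 70611 to 97033 in CBE12mut, 72658 to 77755 in CBE1mut, 84797 to 98682 in CBE1inv, 15877 to 37480 in CBE2inv and 11105 to 41433 in CBE2mut. The 12 v-Abl libraries held 935698 junctions, with V plus D joins at 97.5% or more of each library. Untreated v-Abl libraries held 139267 to 175957 junctions in WT and 82947 to 131524 in 3CBEdel. Treated libraries held 21856 to 31275 and 13180 to 22105. Levels are given as junctions per 100000 junctions of the library, as mean ± SD over 3 libraries.

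The first question was how much each IGCR1 CBE limits V joining in bone marrow pro-B cells. In WT cells 34.2% ± 3.38 (SD, n = 3) of V plus D joins were V joins. Mutation of both CBEs raised the V share to 86.7% ± 1.77, and mutation of CBE1 alone raised it to 72.6% ± 0.957. Inversion of CBE1 gave 47.0% ± 1.44, mutation of CBE2 gave 45.9% ± 7.97 and inversion of CBE2 gave 44.5% ± 4.94. The differences from WT were 52.5, 38.4, 12.8, 11.7 and 10.3 percentage points, and in each of these 5 comparisons every mutant library lay above every WT library. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow. CBE1inv lay below CBE1mut by −25.6 points (exact p = 0.1), and CBE2inv and CBE2mut differed by −1.36 points (exact p = 0.8), less than the spread within either group. That last difference turned to 3.20 points without CBE2mut replicate 1 and to 0.831 points without CBE2inv replicate 1. Over the 6 genotypes the permutation test of the variance between group means gave p = 2e-05. The CBE2mut and CBE2inv libraries came from a run with no WT library, so their genotype and run cannot be told apart in any comparison with WT.

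**Figure D1:**
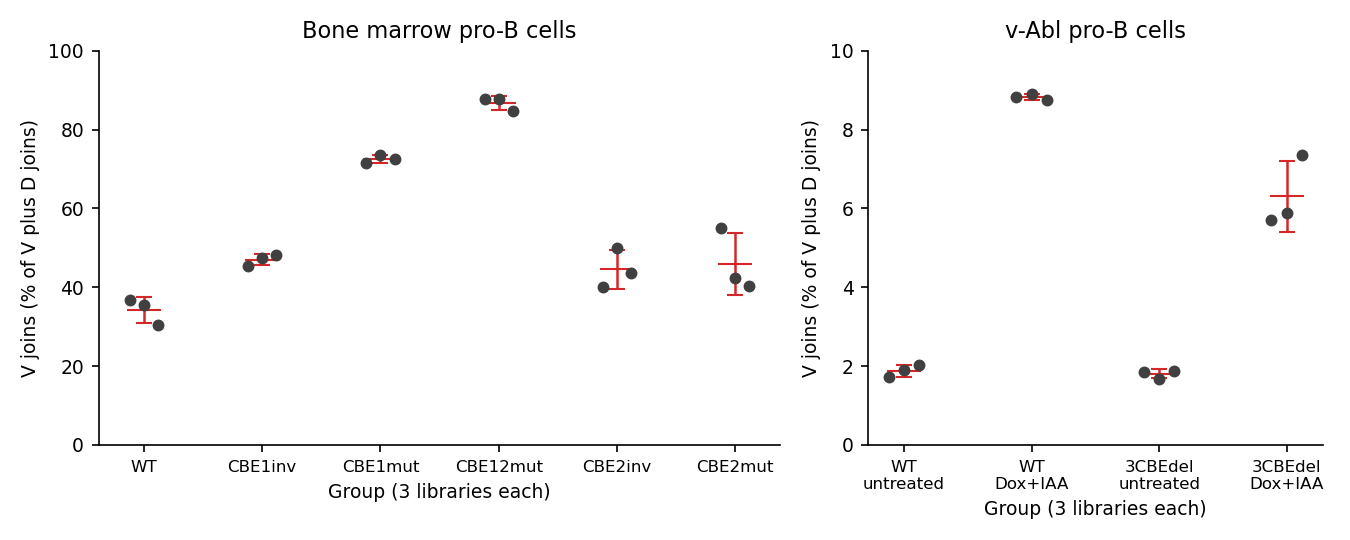
V joins as a percentage of V plus D joins in each library (points) with group mean and SD (bars), bone marrow genotypes on the left and v-Abl groups on the right, on separate axes. The 3 CBE12mut libraries lie between 84.7% and 87.7% and the 3 WT bone marrow libraries between 30.4% and 36.7%, while the 3 treated WT v-Abl libraries lie between 8.76% and 8.91%.

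In CBE12mut pro-B cells, V joins concentrated on Ighv5-2 and its neighbours Ighv5-1 and Ighv2-2. Ighv5-2 (VH81X, chromosome 12, 114836377 to 114836863 on the bone marrow target), the functional V segment nearest to D, took 63236 ± 2015 junctions per 100000 against 3588 ± 309 in WT (log2 change 4.16, SE 0.09, limma adjusted p = 2.19e-36). Ighv5-1, a pseudogene and the V segment nearest to D of all, rose from 168 ± 33.7 to 6229 ± 232 (5.24, adjusted p = 1.53e-25), and Ighv2-2 rose from 2013 ± 226 to 6913 ± 401 (1.79, adjusted p = 3.84e-19). A D segment at 114784064, closest in sequence to Ighd3-1 and lying between the main D group and the V segments, rose from 3.77 ± 6.53 to 341 ± 137 (7.55, adjusted p = 7.84e-09). Ighd1-1 (DFL16.1, 114734544 to 114734566), the D segment farthest from JH in the main D group, fell from 14046 ± 1187 to 312 ± 68.5 (−5.48, adjusted p = 7.54e-28). For each of these 5 segments all 3 CBE12mut libraries lay on one side of all 3 WT libraries.

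Away from the D end, V joins made up a smaller part of CBE12mut libraries. The nearest part of the V region rose to 81467 ± 1949 from 18560 ± 1236 (log2 2.14, adjusted p = 3.51e-12), and the farthest part fell to 952 from 4211 ± 592 (−2.14, adjusted p = 1.01e-05). Of the 160 segments tested with limma voom, 6 rose and 140 fell. The falls depended on the scaling, and the median log2 change of all 160 segments was −2.02 relative to all junctions and −0.07 under median-of-ratios scaling, which called 15 rises and 5 falls. Ighv5-2 (6.10), Ighv5-1 (7.21), Ighv2-2 (3.75) and Ighd1-1 (−3.55) kept their direction under that scaling. Ighd4-1 (DQ52, the D segment nearest to JH) changed by −0.71 (adjusted p = 1.23e-06) relative to all junctions but by 1.24 under median-of-ratios scaling, and Ighv5-4 changed by 0.27 (adjusted p = 0.0707), which passed the threshold without WT replicate 2 (0.39, adjusted p = 0.0197). Among the 10 V segments nearest to D, 3 rose and 6 fell, the same adjusted over the list alone. That list's median was −0.99 and its mean 0.06, its median was 0.98 under median-of-ratios scaling, and camera ranked it above the other segments (adjusted p = 2.51e-05, and 0.0342 with an estimated correlation). No other of the 11 lists passed camera's threshold. The Ighv5 family had 2 risers and 16 fallers of 19, with a median of −1.68 that turned to 0.28 under median-of-ratios scaling, and of 60 Ighv1 segments 56 fell (median −2.19, and −0.23 under that scaling).

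**Figure D2:**
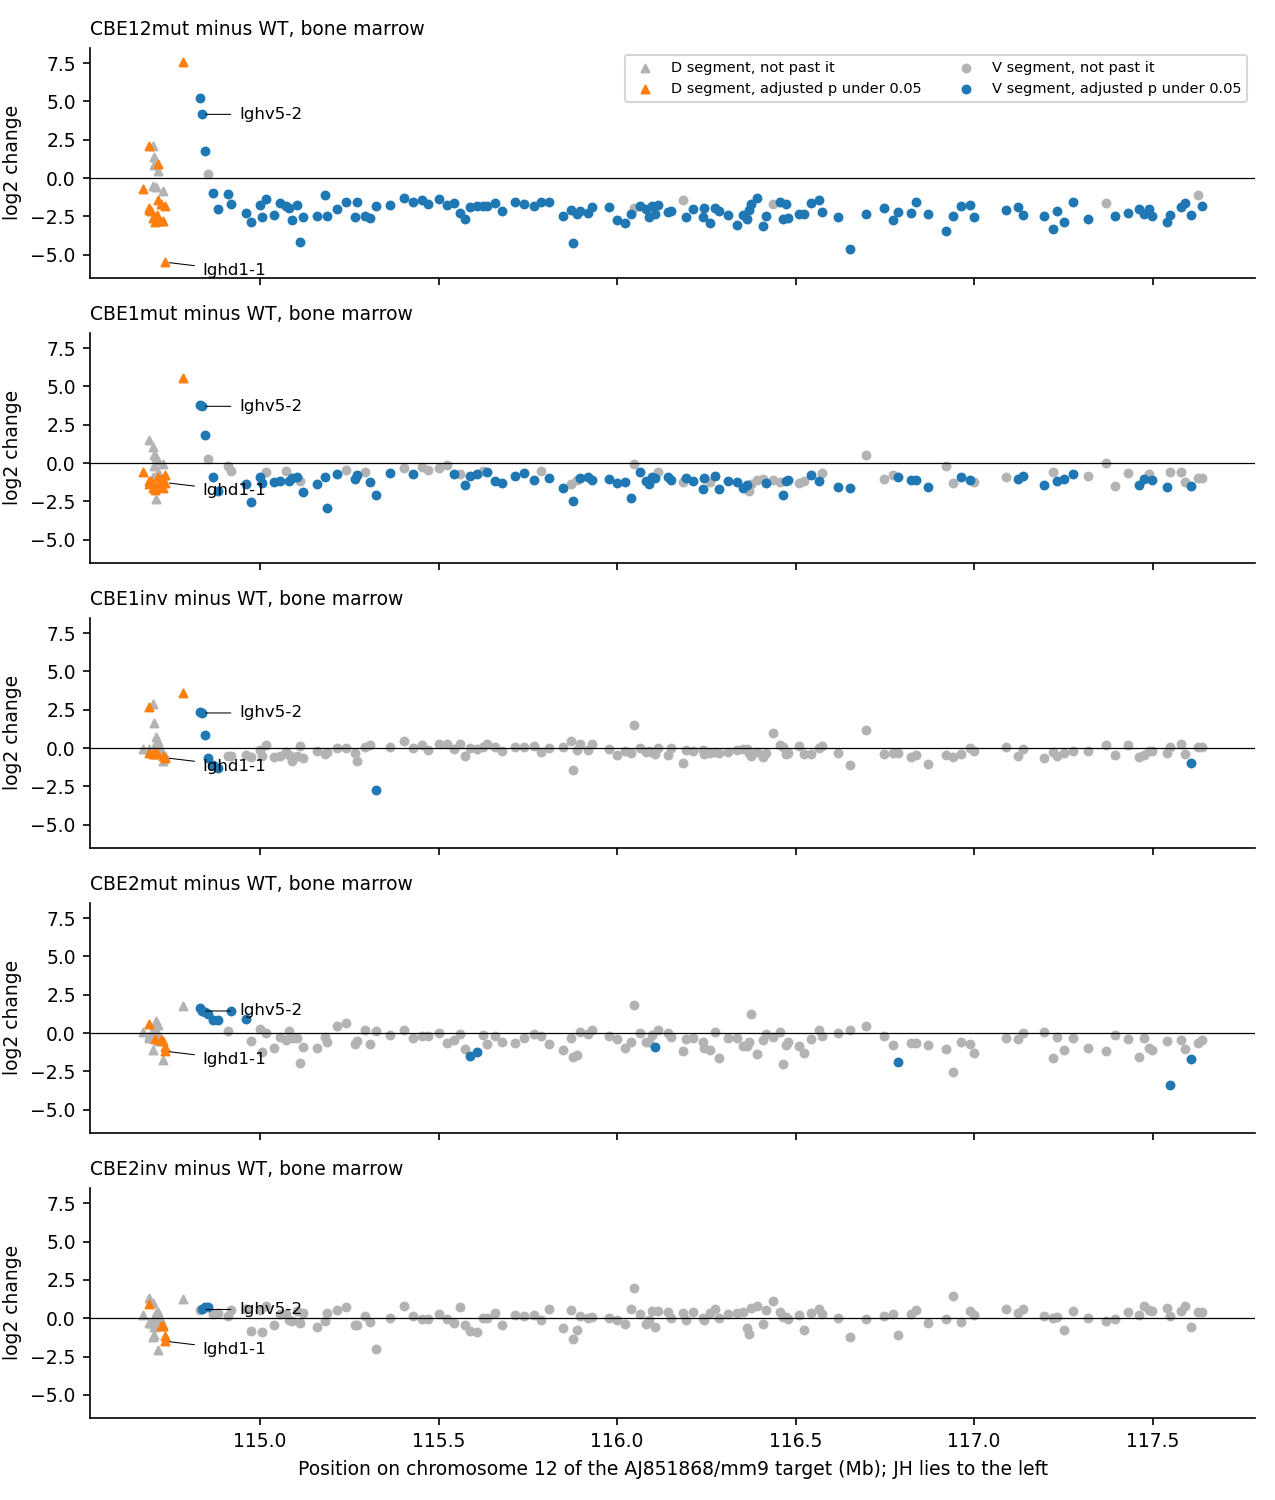
Log2 change of each tested D and V segment (points) against its position on chromosome 12 of the bone marrow target in Mb, for the genotypes against WT, relative to all junctions of a library. Ighv5-2 stands at 4.16 in CBE12mut, 3.70 in CBE1mut and 2.29 in CBE1inv, while the median of all segments in CBE12mut is −2.02 and becomes −0.07 under median-of-ratios scaling, where Ighd4-1 turns from −0.71 to 1.24.

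Mutation of CBE1 alone raised joins of Ighv5-2, Ighv5-1 and Ighv2-2. Ighv5-2 rose to 46231 ± 2129 junctions per 100000 (log2 3.70, adjusted p = 2.88e-34), Ighv5-1 to 2301 ± 146 (3.80, adjusted p = 3.15e-19) and Ighv2-2 to 7167 ± 548 (1.85, adjusted p = 3.15e-19). The D segment at 114784064 rose to 86.4 ± 28.2 (5.54, adjusted p = 1.47e-05). Ighd1-1 fell to 5811 ± 149 (−1.27, adjusted p = 2.28e-17), a change of −0.27 that did not pass under median-of-ratios scaling (adjusted p = 0.684). The nearest part of the V region reached 63859 (1.78) while the middle part changed by −1.04 and the farthest part by −1.05. Overall 4 segments rose and 97 fell, with a median of −1.02 that became −0.02 under median-of-ratios scaling, which called 7 rises and 0 falls (limma voom; 114 segments were under an unadjusted p of 0.05 in the main scaling, and limma trend called 70). The 10 V segments nearest to D held 3 risers and 4 fallers, the same adjusted over the list alone; camera put the list up (adjusted p = 9.9e-05, and 0.0554 with an estimated correlation) although its median was −0.35, which became 0.66 under median-of-ratios scaling, and its mean was 0.22. The other 10 lists did not pass. Ighd4-1 changed by −0.58 (adjusted p = 9.5e-05) and by 0.43 under median-of-ratios scaling, and Ighv5-4 did not pass (0.24, adjusted p = 0.133).

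The inverted CBE1 was compared with WT and with the mutated CBE1. CTCF binding was not measured in these libraries, so the comparisons cannot separate orientation from a change in binding. In CBE1inv cells Ighv5-2 took 17391 ± 614 junctions per 100000 (log2 2.29 over WT, adjusted p = 1.27e-25), and Ighv5-1 (2.34, adjusted p = 5.99e-11) and Ighv2-2 (0.83, adjusted p = 2.5e-07) also rose. The V segments just beyond them fell: Ighv2-3 to 394 ± 23.5 from 861 ± 55.5 (−1.12, adjusted p = 4.33e-06) and Ighv5-6 to 264 ± 54.8 from 640 ± 68.4 (−1.28, adjusted p = 2.98e-05). Ighv5-4 changed by −0.61 (adjusted p = 0.00527), a call lost without WT replicate 2 (−0.50, adjusted p = 0.0623). Ighd1-1 fell to 9068 ± 359 (−0.63, adjusted p = 2.24e-09), which did not pass under median-of-ratios scaling (−0.44). Overall 5 segments rose and 11 fell with a median of −0.18 (−0.01 under median-of-ratios scaling, with 4 rises and 2 falls), and without WT replicate 3 the total was 9. The D segment at 114784064 rose by 3.62 (adjusted p = 0.0198), a call lost without WT replicate 2 (3.17) or WT replicate 3 (2.60). None of the 11 lists passed camera's threshold (lowest adjusted p 0.6); of the 10 V nearest to D, 3 rose and 3 fell, the same adjusted over the list alone. Ighd4-1 did not pass (−0.08, adjusted p = 0.759; 0.11 under median-of-ratios scaling).

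Set against CBE1mut, CBE1inv held less of 4 of the V segments near D. Ighv5-2 was lower by −1.41 (adjusted p = 4.19e-22), Ighv5-1 by −1.46, Ighv2-2 by −1.02 and Ighv5-4 by −0.85 (adjusted p = 1.45e-05), all 3 CBE1inv libraries below all 3 CBE1mut libraries. Of 160 segments 67 rose and 5 fell, with a median of 0.80 that became −0.01 under median-of-ratios scaling, where 0 rose and 7 fell (limma voom; limma trend in the main scaling called 46 and 88 segments were under an unadjusted p of 0.05). Without CBE1mut replicate 2 the total was 44. Ighd1-1 (0.64) and Ighd4-1 (0.50) turned to −0.17 and −0.32 under median-of-ratios scaling. The 10 V nearest to D went down by camera (adjusted p = 1.07e-09, and 0.00239 with an estimated correlation; 2 rose and 4 fell, the same adjusted over the list alone; median −0.24). Lists that passed only at the preset correlation were all D (up, adjusted p = 0.0158), the Ighv5 family (down, 0.0191, although its median was 0.69 and turned to −0.14 under median-of-ratios scaling) and the nearest V part (down, 0.0319, median 0.69, also −0.14 under that scaling).

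In CBE2mut libraries 8 of the 10 V segments nearest to D were higher than in WT. These libraries, like those of CBE2inv, came from a run with no WT library. Genotype and run cannot be told apart in either comparison with WT. In CBE2mut cells Ighv5-2 took 9708 ± 304 junctions per 100000 (log2 1.45, adjusted p = 6.24e-15), Ighv2-2 5146 ± 217 (1.37, adjusted p = 1.36e-11), Ighv5-4 2643 ± 85.3 (1.22, adjusted p = 2.92e-08) and Ighv5-1 506 ± 89.4 (1.66, adjusted p = 2.05e-05). Ighv2-3 (1564 ± 114, 0.86) and Ighv5-6 (1149 ± 109, 0.84) rose as well. Ighd1-1 fell to 6351 ± 990 (−1.18, adjusted p = 4.57e-12), and Ighd4-1 did not pass (0.05, adjusted p = 0.813; −0.05 without CBE2mut replicate 3). Of the 10 V segments nearest to D, 8 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 7.56e-19, and 5.34e-05 with an estimated correlation). The Ighv5 family also went up (6 risers of 19, adjusted p = 2.9e-06, and 0.00627 with an estimated correlation), and the nearest V part passed only at the preset correlation (0.00781 against 0.334, with a median of −0.23 that turned to 0.16 under median-of-ratios scaling). Overall 9 segments rose and 11 fell. The total was 33 without CBE2mut replicate 1 and 11 without CBE2mut replicate 3, and median-of-ratios scaling moved the median from −0.35 to 0.01 and called 11 rises and 2 falls. Scaling to V plus D joins called 9 rises and 7 falls.

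In CBE2inv cells 3 of the V segments nearest to D rose. Ighv5-2 took 5259 ± 1074 (log2 0.57, adjusted p = 0.00146), Ighv2-2 3240 ± 215 (0.70, adjusted p = 0.000897) and Ighv5-4 1838 ± 159 (0.71, adjusted p = 0.00382), and none of these 3 passed under median-of-ratios scaling (0.48, 0.63 and 0.61). Ighd1-1 fell to 5024 ± 829 (−1.49 in the zone test of the last D, adjusted p = 3.07e-06). Ighd4-1 did not pass (0.18, adjusted p = 0.503). The largest rise was that of a D segment at 114687612, closest in sequence to Ighd3-2 (0.91, adjusted p = 0.000594), which did not pass under median-of-ratios scaling (0.92, adjusted p = 0.082). In all 4 segments rose and 4 fell (0 and 3 under median-of-ratios scaling, 4 and 1 scaled to V plus D joins; the total was 5 without CBE2inv replicate 2). The 10 V nearest to D (3 risers, 4 adjusted over the list alone; adjusted p = 0.00233), the Ighv5 family (up, 0.0066) and all D (down, 0.000456) passed camera at the preset correlation, each at 0.0953 with an estimated correlation. Within the shared run, CBE2inv held less Ighv5-2 than CBE2mut (−0.88, adjusted p = 1.37e-06) and less Ighv2-2 (−0.67, adjusted p = 0.00367; 0.0569 without CBE2inv replicate 2). Ighd1-1 (−0.32, adjusted p = 0.219), Ighv5-4 (−0.51, adjusted p = 0.0964) and Ighd4-1 (0.13, adjusted p = 0.675) did not pass, and without CBE2mut replicate 1 Ighd1-1 (−0.46) and Ighv5-4 (−0.49) did. Between these 2 groups 3 segments rose and 3 fell. That total was 32 without CBE2mut replicate 1, 1 without CBE2inv replicate 2, 3 without CBE2inv replicate 3 and 2 without CBE2mut replicate 3, so it rested on single libraries, and median-of-ratios scaling called 3 rises and 7 falls. The 10 V nearest to D went down (3 fallers, 5 adjusted over the list alone; camera adjusted p = 1.43e-14, and 0.00027 with an estimated correlation). The 6 other lists past the preset threshold, all D, the Ighv5, Ighv2 and Ighv1 families and the nearest and farthest V parts, reached no lower than 0.122 with an estimated correlation.

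Both CBE2 genotypes held more junctions between JH4 and other JH segments. The JH zone held 1937 ± 234 junctions per 100000 in WT, 7449 ± 2277 in CBE2mut (log2 1.90, adjusted p = 0.000194) and 9479 ± 6083 in CBE2inv (2.12, adjusted p = 9.82e-05). Most of these junctions had the orientation opposite to deletional joining: 1869 ± 263 in WT, 7135 ± 2326 in CBE2mut and 9001 ± 6155 in CBE2inv, where the 3 libraries held 5094, 16097 and 5813 (exact p = 0.1 for each against WT). In CBE12mut they were at 1374 ± 159 and in CBE1inv at 2497 ± 244 (exact p = 0.1 each), and in CBE1mut at 1569 ± 94.5 (exact p = 0.2). CBE12mut also lacks CBE2 and shared the run of WT, and its JH zone held 1436 ± 151 (log2 −0.43, adjusted p = 0.275). D joins were fewer in the mutants, and per 100 D joins the JH junctions were 3.05 ± 0.294 in WT, 11.2 ± 1.71 in CBE12mut, 6.16 ± 0.404 in CBE1mut, 5.04 ± 0.485 in CBE1inv, 14.9 ± 2.99 in CBE2mut and 20.8 ± 16.7 in CBE2inv, where 2 libraries were at 9.76 and 12.6 and replicate 2 far above them (exact p = 0.1 each against WT). This ratio thus rose as well in the genotypes with an intact CBE2. The genotype and the run of the CBE2 libraries cannot be told apart here.

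**Figure D3:**
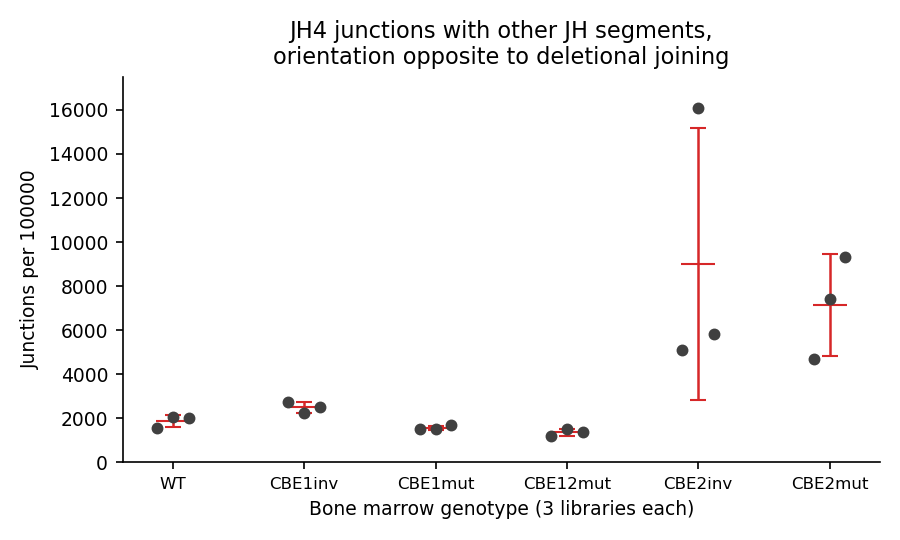
Junctions of JH4 with other JH segments in the orientation opposite to deletional joining, per 100000 junctions, for each bone marrow library (points) with group mean and SD (bars). The 3 CBE2inv libraries lie at 5094, 16097 and 5813, and the WT mean is 1869.

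D usage was compared among D joins and inside V joins, where a run of D sequence could be read in 64.4% to 69.6% of joins per bone marrow library. Ighd1-1 made up 22.1% ± 1.11 of D joins in WT, 2.38% ± 0.211 in CBE12mut, 12.8% ± 0.567 in CBE2mut, 10.2% ± 0.916 in CBE2inv and 17.9% ± 0.266 in CBE1inv (exact p = 0.1 for each against WT). In CBE1mut it stayed at 21.8% ± 0.498 (exact p = 0.7). Inside V joins Ighd1-1 made up 19.6% ± 0.206 in WT, 2.76% ± 0.0106 in CBE12mut, 13.4% ± 0.191 in CBE1mut, 13.5% ± 0.392 in CBE1inv, 9.03% ± 0.994 in CBE2mut and 9.17% ± 0.738 in CBE2inv, each below WT in all 3 libraries (exact p = 0.1). Ighd4-1 inside V joins was at 2.43% ± 0.352 in WT and 3.71% ± 0.332 in CBE12mut. Among D joins its share was higher in CBE12mut, at 15.6%, 17.2% and 17.6% by library, against 5.83%, 5.37% and 5.67% in WT. Libraries of the other genotypes lay between 6.35% (CBE1inv replicate 1) and 9.37% (CBE2inv replicate 3). No test was run on this share. Of the joins that fell between the D and V segments, 97.4% ± 2.15 lay within 5 kb of Ighd1-1 in WT, against 3.01% ± 2.11 in CBE12mut, 50.0% ± 8.01 in CBE1mut, 90.6% ± 2.11 in CBE1inv and 78.5% ± 11.7 in CBE2mut (exact p = 0.1 each), and 95.1% ± 6.69 in CBE2inv (exact p = 0.8). The CBE2mut and CBE2inv shares rested on only 167 and 95 joins. CBE2mut replicate 3 lay at 65.0%, against 84.7% and 85.7% in replicates 1 and 2. For both genotypes, genotype and run cannot be told apart in the comparisons with WT. The D segment at 114784064 lies in this interval and held 864 of the 1482 joins there in CBE12mut, 195 of 728 in CBE1mut and 9 of 965 in WT. Without its joins the shares were 98.7% ± 0.673 in WT, 6.10% ± 3.58 in CBE12mut and 68.2% ± 7.78 in CBE1mut (exact p = 0.1 each).

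**Figure D4:**
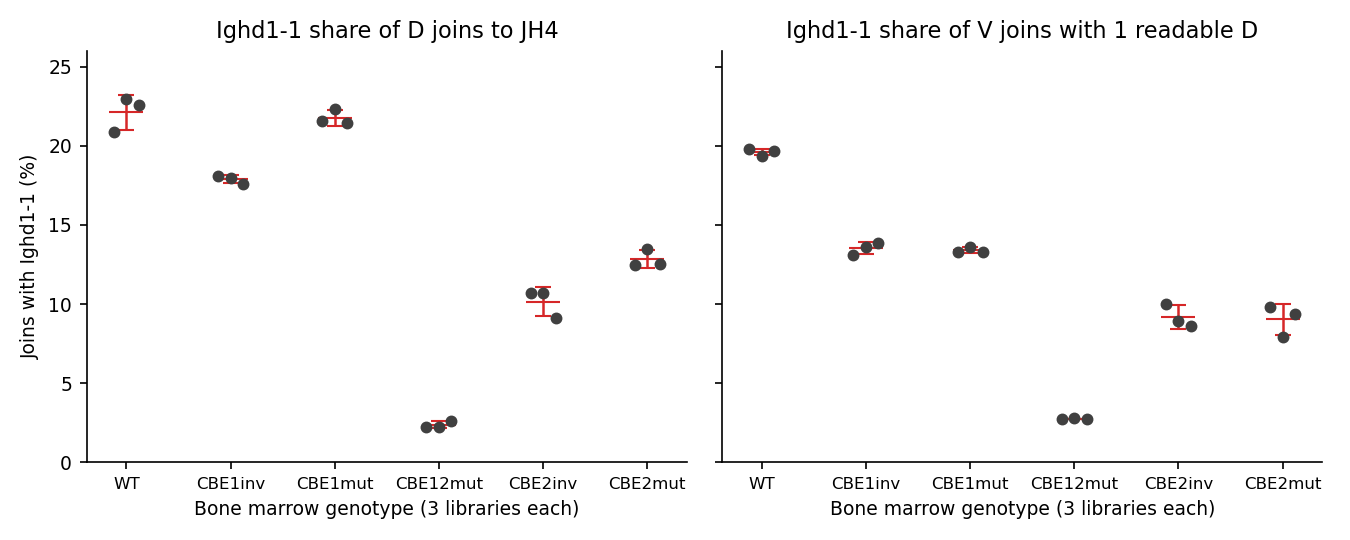
Percentage of D joins (left) and of V joins with a readable D (right) that used Ighd1-1, for each bone marrow library (points) with group mean and SD (bars). In CBE12mut the means are 2.38% and 2.76%, and in WT 22.1% and 19.6%; CBE1mut is near WT among D joins (21.8%) and below it inside V joins (13.4%).

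The reading frame of V joins differed between V segments in WT bone marrow. Ighv5-2 joins were in frame in 28.6% ± 1.94 and Ighv2-2 joins in 31.8% ± 2.12, while V joins other than Ighv5-2 were in frame in 53.2% ± 1.54. In CBE12mut the shares were 26.2% ± 0.70 for Ighv5-2 and 39.6% ± 1.75 for the other V segments, each below WT in all 3 libraries (exact p = 0.1). The mix of segments in this class changed, as Ighv5-1 and Ighv2-2 made up 61.4% of the other V joins in CBE12mut and 7.44% in WT. Without Ighv5-1, Ighv5-2, Ighv2-2 and Ighv5-4, the share rose from 55.7% ± 1.07 in WT to 64.2% ± 1.45 in CBE12mut (exact p = 0.1), while that of Ighv2-2 fell to 22.2% ± 2.14 (exact p = 0.1). In untreated WT v-Abl cells, Ighv5-2 joins were in frame in 34.8% ± 3.49 and other V joins in 35.1% ± 1.10.

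The v-Abl lines asked whether loss of WAPL, which lengthens loop extrusion, opens the V region, and whether the 3' CBE array takes part. In untreated WT cells the V share was 1.88% ± 0.158, and in treated WT cells 8.84% ± 0.0758. In 3CBEdel cells it was 1.80% ± 0.113 untreated and 6.31% ± 0.902 treated. With reads of the same coordinates collapsed, the means were 5.83% and 13.5% in WT and 5.53% and 9.67% in 3CBEdel. Treatment added 6.96 points in WT and 4.51 points in 3CBEdel (exact p = 0.1 each), and permuting treatment within genotype gave 5.73 points (exact p = 0.005, the smallest of 400 relabelings). In WT, D joins per library were 135035, 136150 and 169995 untreated and 19429, 27844 and 25790 treated. V joins were 2353, 2633 and 3517 untreated and 1882, 2725 and 2477 treated. In 3CBEdel each treated library held fewer joins of both kinds than each untreated one. Junctions were not counted per cell, so the V share does not tell more V joining from fewer D joins. Treated 3CBEdel lay below treated WT by −2.53 points (exact p = 0.1), and the untreated lines differed by −0.0760 points (exact p = 0.4), which was within the spread. The difference between both treatment effects was −2.45 points (exact p = 0.085 with genotype permuted within treatment), which did not pass 0.05. The treated libraries of both lines did not overlap, so this p turned on how the small untreated difference ranked among its relabelings. It does not argue against a difference between the treatment effects. Within the run that 8 libraries shared, treatment added 6.88 points in WT and 4.02 points in 3CBEdel, and treated 3CBEdel lay below treated WT by −3.05 points.

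Relative to all junctions, treatment of WT v-Abl cells lowered Ighd1-1 and Ighv5-2 and raised Ighd4-1 and distant V segments. Ighd4-1 (114668739 in mm9) rose from 1885 ± 132 to 10837 ± 130 junctions per 100000 (log2 2.52, adjusted p = 5.91e-15), and Ighd1-1 (114720381) fell from 70854 ± 832 to 30560 ± 308 (−1.21, adjusted p = 2.49e-13). Over the 3 libraries of a group, Ighd4-1 held 8904 junctions treated and 8640 untreated, and Ighd1-1 held 25098 and 322744. Ighd4-1 thus rose in its share of junctions with little change in its count. Ighv5-2 (114816715 to 114817201) fell from 836 ± 45.3 to 336 ± 86.7 (−1.31, adjusted p = 1.57e-05). Ighv1-70 (116930100) rose from 1.80 ± 2.01 to 453 ± 96.7 (8.36, adjusted p = 4.42e-08). This segment was placed from a join cluster and named by gene order, and its closest annotated sequence is Ighv1-77. Ighv1-75, with no junction in the untreated libraries, was at least 157-fold higher than a floor of 3 junctions over that group. The farthest V part rose from 45.6 ± 15.2 to 4043 ± 200 (6.49) and the middle part from 68.9 ± 21.4 to 2441 ± 178 (5.17). The nearest part held 1763 ± 129 and 2888 ± 281 (0.71), a direction that turned to −0.35 when reads with the same coordinates were collapsed.

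Of 78 segments in WT v-Abl cells, 61 rose and 4 fell with treatment. The median was 4.86, and 2.73 under median-of-ratios scaling, which called 46 rises and 18 falls. All 27 tested Ighv1 segments rose (camera adjusted p = 0.00183, and 0.106 with an estimated correlation), as did all 21 of the farthest V part (0.00139 and 0.084), all 17 of the middle part, all 6 Ighv8 segments and all 17 of the other V families, and the lists of the last 3 did not pass camera. The 8 tested of the 10 V nearest to D had 0 risers and 3 fallers (1 adjusted over the list alone) and went down (adjusted p = 8.74e-08, and 0.00682 with an estimated correlation). Those 3 were Ighv5-2, Ighv2-2 (−0.73, adjusted p = 0.0323) and Ighv5-4 (−0.80, adjusted p = 0.0412). The call of Ighv2-2 was lost without untreated replicate 2 (−0.67) or 3 (−0.68) or treated replicate 1 (−0.50) or 3 (−0.69), and that of Ighv5-4 without untreated replicate 2 (−0.75) or treated replicate 1 (−0.61), 2 (−1.01) or 3 (−0.79). The nearest V part was down against the other segments (4.3e-05, and 0.0176), with a median of 1.93 that turned to −0.18 under median-of-ratios scaling. The Ighv5 family (0.000616, and 0.0426) and the Ighv2 family (0.000351, and 0.0426) were down as well, the former with a median of 0.68 that turned to −1.48 under that scaling and the latter with a median of −0.73 and a mean of 0.16. The filter shaped these counts. The untreated libraries alone would have kept 23 of the 66 tested V segments, among them 2 of the 27 Ighv1 segments and 1 of the 21 in the farthest part, and the others could be tested only because treated libraries held them. Of those 23, 10 rose and 3 fell, so the statement that all segments of a list rose decides little beside the zone test, which uses no filter. The same holds for camera, which ranked the lists near D against segments that mostly passed through treated libraries. A list called down there lay below that background, which is no evidence of a fall. Of the 20 nearest-part segments that the untreated libraries alone would have kept, 7 rose and 3 fell (median 1.28). The D list (8 risers, 1 faller of 12; median 1.28, and −0.85 under that scaling) and the pseudogenes (4 risers of 5) did not pass.

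**Figure D5:**
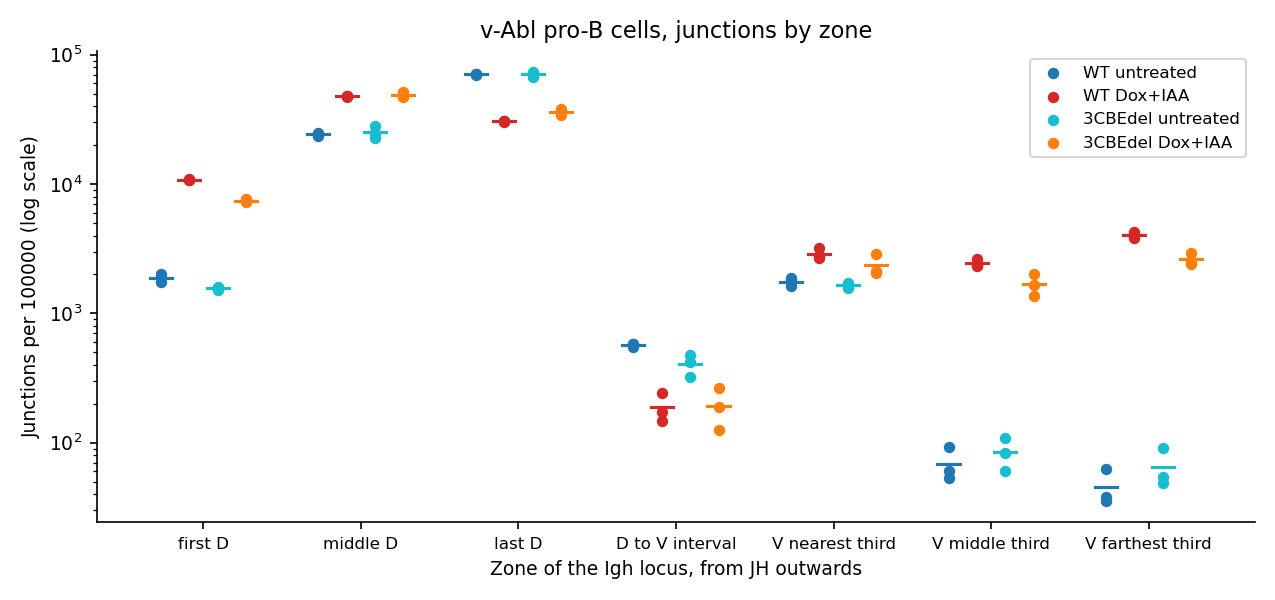
Junctions per 100000 (log axis) in the zones of the Igh locus from JH outwards, for each v-Abl library (points) in the 4 groups. The farthest V part holds 45.6 in untreated and 4043 in treated WT cells on average, and 64.4 and 2637 in 3CBEdel cells; the rise of the nearest part in WT (0.71) turns to −0.35 when reads with the same coordinates are collapsed.

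The same treatment of 3CBEdel cells shifted the same zones. Ighd4-1 rose from 1563 ± 39.2 to 7412 ± 203 (log2 2.24, adjusted p = 1.69e-12), Ighd1-1 fell from 70471 ± 2889 to 35840 ± 1886 (−0.98, adjusted p = 1.96e-11) and Ighv5-2 fell from 548 ± 46.0 to 308 ± 16.9 (−0.82, adjusted p = 0.00654). Over the 3 libraries of a group, Ighd4-1 held 4156 junctions treated and 5357 untreated, and Ighd1-1 held 20070 and 240701. Ighd4-1 thus rose in its share of junctions and not in its count. Ighv2-2 fell by −1.28 (adjusted p = 0.00883), a call lost without 3CBEdel treated replicate 2 (−1.09), and Ighv5-4 did not pass (−0.59, adjusted p = 0.131) but passed with reads of the same coordinates collapsed (−1.21, adjusted p = 0.00116). The farthest V part rose from 64.4 ± 22.7 to 2637 ± 272 (5.38) and the middle part from 84.4 ± 24.5 to 1676 ± 323 (4.32), and the nearest part changed by 0.49, or by −0.50 when reads with the same coordinates were collapsed. Of 78 segments 58 rose and 4 fell, with a median of 3.77 (2.11 under median-of-ratios scaling, with 39 rises and 14 falls). All 27 Ighv1 segments rose (camera adjusted p = 0.00229, and 0.104 with an estimated correlation), as did all 21 of the farthest part (0.00229 and 0.0965), again mostly segments tested through treated libraries; of the 23 V segments that the untreated libraries alone would have kept, 8 rose and 3 fell. The 8 tested of the 10 V nearest to D had 3 fallers (2 adjusted over the list alone; 3.19e-07, and 0.00876), the nearest V part was down (5.28e-06, and 0.00876) with a median of 0.99 that turned to −0.68 under median-of-ratios scaling, and the Ighv5 family was down (1.75e-05, and 0.00876). The Ighv2 family was down at the preset correlation only (0.0117 against 0.133), with a mean of 0.48. As in WT, camera ranked these lists against segments that mostly passed the filter through treated libraries, which is no evidence of a fall. Of the 20 nearest-part segments that the untreated libraries alone would have kept, 5 rose and 3 fell (median −0.04). Neither all D (median 1.45, and −0.26 under median-of-ratios scaling), the Ighv8 family, the other families, the middle part nor the pseudogenes passed.

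The last comparison set 3CBEdel against WT at the same treatment. In untreated cells Ighv5-2 was lower in 3CBEdel (548 ± 46.0 against 836 ± 45.3, log2 −0.62, adjusted p = 0.00333) and Ighv5-12 higher (101 ± 18 against 42.6 ± 0.667, log2 1.198, adjusted p = 0.0147). These were the only calls among 78 segments with limma voom, where 14 were under an unadjusted p of 0.05, and limma trend called 0. Within the shared run neither passed (−0.69 with adjusted p = 0.0696, and 1.12 with adjusted p = 0.238), and the call of Ighv5-12 was also lost without 3CBEdel untreated replicate 1 (1.12) or replicate 3 (1.12). The total of 2 was 1 without either of those libraries and 4 without 3CBEdel untreated replicate 2. Ighd4-1 (−0.27, adjusted p = 0.0714), Ighd1-1 (−0.01), Ighv2-2 (−0.19) and Ighv5-4 (0.28) did not pass, and without WT untreated replicate 1 Ighd4-1 did (−0.32, adjusted p = 0.019). The zone test called 2 of 11 zones, both lower in 3CBEdel: the JH zone (272 ± 23.5 against 458 ± 14.1, log2 −0.75, adjusted p = 0.00407), which turned to 0.04 with the deletional orientation only, and the first D zone, which holds Ighd4-1 (−0.27, adjusted p = 0.00679). All D went down by camera (adjusted p = 0.000224, and 0.0177 with an estimated correlation; 0 fallers, 2 adjusted over the list alone). In treated cells Ighd4-1 was lower in 3CBEdel (−0.55, adjusted p = 0.00032), the single call among 78 segments, which did not pass under median-of-ratios scaling (−0.16, adjusted p = 0.779). Ighd1-1 was higher by 0.23 with an adjusted p of 0.0545, and limma trend called it (adjusted p = 0.00183). The zone test called 3 zones: the first D (−0.55, adjusted p = 6.19e-05), the last D, which holds Ighd1-1 (0.23, adjusted p = 0.00803), and JH (−0.58, adjusted p = 0.00803), which did not pass with the deletional orientation only (−0.30, adjusted p = 0.725). Ighv5-2 (−0.13), Ighv2-2 (−0.73) and Ighv5-4 (0.48) did not pass. Without 3CBEdel treated replicate 2 the total was 3, and with the replicate number as a block it was 2. The Ighv2 family was up at the preset correlation only (0.0107 against 0.309). For the difference of the treatment effects limma voom called 0 segments, 13 were under an unadjusted p of 0.05 and limma trend called 0. Values were −0.28 for Ighd4-1, 0.23 for Ighd1-1, 0.49 for Ighv5-2, −0.55 for Ighv2-2 and 0.21 for Ighv5-4, and without 3CBEdel untreated replicate 2 Ighd1-1 passed (0.26). The total was 1 without WT untreated replicate 3, without 3CBEdel untreated replicate 2 or with the replicate number as a block. The farthest V part rose less in 3CBEdel (−1.10, adjusted p = 0.0544), the first D zone rose less (−0.28) and the last D zone fell less (0.24), none past the threshold in the zone test, in which 4 zones were under an unadjusted p of 0.05; 4 zones passed without either of those 2 libraries. All D was up at the preset correlation only (0.00999 against 0.0856).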

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

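These counts were looked at only after the main results were seen, and no explanation of them was tested. Junctions outside chromosome 12 are no part of the comparisons above, and the totals of v-Abl Igk, bone marrow Tra and bone marrow Gm4242 each exceed the 3 counts that a count of 0 allows. In v-Abl cells, junctions of the JH4 bait fell in the Igk light-chain locus (chromosome 6, 67505630 to 70676751). There were 377 in untreated WT cells, 57 in treated WT cells, 154 in untreated 3CBEdel cells and 26 in treated 3CBEdel cells. Libraries differed in depth, and per 100000 junctions this was 82.7, 69.4, 45.1 and 46.4. In untreated WT cells it was 55.6% of the 678 junctions outside chromosome 12, or 444 times the number that the length of the locus gives by chance. The same multiple was 117 in treated WT, 248 in untreated 3CBEdel and 75.2 in treated 3CBEdel cells, and it fell with treatment as other junctions outside chromosome 12 rose relative to depth. The bone marrow libraries together held 2 junctions in Igk.

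In bone marrow, 56 junctions fell in the Tra locus (chromosome 14, 53047603 to 54842772), or 90.4 times the number given by its length. A further 83 junctions in 16 of the 18 bone marrow libraries fell at Gm4242 (chromosome 19, 61308686 to 61308793), and 26 of them were in WT, 4 in CBE12mut, 14 in CBE1mut, 21 in CBE1inv, 9 in CBE2inv and 9 in CBE2mut. Per 100000 junctions this was 11.4, 1.65, 6.16, 7.52, 11.3 and 10.7. The window of 2 kb with the most bone marrow junctions outside chromosome 12 lay on chromosome 4 (64808000 to 64809999), with 100 junctions over all 18 libraries. The v-Abl libraries held 0 at Gm4242. No biological explanation was tested for any of these.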

How the results depend on the processing

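Collapsing identical read sequences and keeping only the run that holds bone marrow WT were chosen after the results were seen; the other alternatives were planned. Of 212 alternative values of the V share, 198 kept their direction and side of the threshold. Of these 212 values, 114 were differences between a pair of groups, for which 3 against 3 libraries cannot pass 0.05, so for them this covers direction only (112 kept it), and 58 came from tests that can pass it (57 kept both). The other 40 were group means, of which 29 stayed and 11 moved. So did 2309 of 2588 values of named segments and 663 of 721 values of zones, and 165 of 211 counts of called segments and 122 of 142 counts of called zones stayed within 1.5 times. Where no cause is given for a change, the cause was not tested.

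The V share differences from WT kept their direction in every alternative run. They ranged from 44.3 to 53.8 points in CBE12mut, 29.9 to 39.7 in CBE1mut, 9.98 to 14.1 in CBE1inv, 7.14 to 14.5 in CBE2mut and 7.67 to 12.5 in CBE2inv. In v-Abl cells the treatment effect ranged from 6.87 to 7.66 points in WT and from 3.99 to 4.81 in 3CBEdel, and the difference between treated lines from −3.82 to −2.22. CBE2inv minus CBE2mut ranged from −4.15 to 3.20 as single libraries were left out, with 0.831 without CBE2inv replicate 1 and 3.20 without CBE2mut replicate 1. The treatment effect within genotype was 5.45 points in the shared run, where the exact p was 0.0556, the smallest that its fewer libraries allow. With reads of the same coordinates collapsed, group means moved to 79.3% in CBE12mut, 64.9% in CBE1mut, 45.0% in CBE1inv, 5.83% in WT untreated, 13.5% in WT treated, 5.53% in 3CBEdel untreated and 9.67% in 3CBEdel treated. With identical read sequences collapsed, they moved to 2.96%, 10.4%, 2.66% and 7.35% in the 4 v-Abl groups.

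Median-of-ratios scaling called 20 segments in CBE12mut, 7 in CBE1mut, 6 in CBE1inv, 13 in CBE2mut, 3 in CBE2inv, 7 for CBE1inv minus CBE1mut, 10 for CBE2inv minus CBE2mut and 0 for 3CBEdel minus WT untreated. It reversed Ighd4-1 in CBE12mut (1.24), CBE1mut (0.43), CBE1inv (0.11), CBE1inv minus CBE1mut (−0.32), CBE2inv minus CBE2mut (−0.20) and the difference of treatment effects (0.14), Ighd1-1 in CBE1inv minus CBE1mut (−0.17), and Ighv5-2 in 3CBEdel minus WT treated (0.30). By its construction this scaling takes as no change the typical segment among those with junctions in every library. Over all tested segments its medians were −0.07 to 0.08 in the bone marrow contrasts. For treatment in v-Abl cells they were 2.73 in WT and 2.11 in 3CBEdel.

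Limma trend called 9 segments in CBE1inv, 46 for CBE1inv minus CBE1mut, 0 for 3CBEdel minus WT untreated and 2 for treated. Fits of only the 2 groups compared called 11 in CBE2mut, 3 for CBE2inv minus CBE2mut, 31 for 3CBEdel treated minus untreated, and 8 and 4 for 3CBEdel minus WT untreated and treated. With the same coordinates collapsed, 13 were called in CBE2mut, and 8 and 4 for 3CBEdel minus WT untreated and treated. With identical reads collapsed the latter 2 counts were 5 and 4. Scaling to V plus D joins, and the deletional orientation only, each called 5 in CBE2inv. Without the filter 107 segments were called for treatment in WT and 105 in 3CBEdel, since more segments were tested. The filter kept 66 V segments in v-Abl cells, and the untreated libraries alone would have kept 23 of them, so it favoured segments that rose. For 3CBEdel minus WT untreated the shared run called 0 and the run as a block 1, and for treated the run as a block called 2.

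In the zone test, only the run that holds WT called 6 zones in CBE1inv and 8 for CBE1inv minus CBE1mut. The same coordinates collapsed gave 3 for CBE1inv minus CBE1mut, 1 for CBE2inv minus CBE2mut and 3 for the difference of treatment effects. CBE2inv minus CBE2mut also had 1 zone with the deletional orientation only, with identical reads collapsed, scaled to V plus D joins and with a pseudocount of 0.5. The deletional orientation gave 1 zone for 3CBEdel minus WT untreated and 4 for the difference of treatment effects, and identical reads collapsed gave 5 for 3CBEdel minus WT treated. With the same coordinates collapsed, treatment reversed the JH zone (−0.35 against 0.63) and the nearest V part (−0.35 against 0.71) in WT, and the JH zone (−0.25 against 0.81) and the nearest V part (−0.50 against 0.49) in 3CBEdel. The JH zone of 3CBEdel minus WT untreated, called at −0.75, was 0.0385 with the deletional orientation only, so that call was lost and its direction turned; for treated cells the called −0.58 became −0.30 and did not pass. Ighd1-1 in that contrast was 0.0718 with the same coordinates collapsed and 0.0301 with identical reads collapsed.

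Leaving out 1 library at a time gave 134 to 146 called segments in CBE12mut, 75 to 106 in CBE1mut, 56 to 65 for treatment in WT and 55 to 61 in 3CBEdel. CBE1inv ranged from 9 (without WT replicate 3) to 15. CBE2mut ranged from 11 (without CBE2mut replicate 3) to 33 (without CBE2mut replicate 1), and CBE2inv from 5 (without CBE2inv replicate 2) to 9. CBE1inv minus CBE1mut ranged from 44 (without CBE1mut replicate 2) to 63. CBE2inv minus CBE2mut ranged from 1 (without CBE2inv replicate 2) to 32 (without CBE2mut replicate 1), with 3 without CBE2inv replicate 3 and 2 without CBE2mut replicate 3. For 3CBEdel minus WT the range was 1 (without 3CBEdel untreated replicate 1 or 3) to 4 (without replicate 2) untreated and 1 to 3 (without 3CBEdel treated replicate 2) treated, and 0 to 1 (without WT untreated replicate 3 or 3CBEdel untreated replicate 2) for the difference of treatment effects. Called zones ranged from 3 to 5 in CBE2mut (5 without CBE2mut replicate 1), 4 to 7 in CBE2inv (7 without CBE2inv replicate 2), 1 to 5 for CBE2inv minus CBE2mut (5 without CBE2mut replicate 1, and 1 without CBE2inv replicate 1 or CBE2mut replicate 2 or 3) and 0 to 4 for the difference of treatment effects (4 without WT untreated replicate 3 or 3CBEdel untreated replicate 2). Ighd4-1 in CBE2mut ranged from −0.0508 (without CBE2mut replicate 3) to 0.106, Ighd1-1 in 3CBEdel minus WT untreated from −0.0365 to 0.0226 (without 3CBEdel untreated replicate 1), and Ighv5-2 in 3CBEdel minus WT treated from −0.286 to 0.0529 (without WT treated replicate 3).

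The labels do not say that equal replicate numbers pair libraries. Deviations of same-numbered libraries correlated above 0.1 in 14 of 45 bone marrow pairs and 4 of 18 v-Abl pairs, and 6 of 18 and 8 of 12 libraries correlated best with their own number, so the numbers were not taken as pairs. With the replicate number as a block, 3CBEdel minus WT treated had 2 called segments in place of 1 and the difference of treatment effects 1 in place of 0, and no other count of called segments moved by over 1.5 times. Pairing cannot move the mean treatment effect on the V share (5.73 points), so that value says nothing about pairing. In simulated WT treatment data 17.5% of 2-fold and 57.5% of 4-fold changes were called. How much of this comes from depth and how much from the spread between libraries was not tested. Depth alone left a library's V share known to within ± 0.962 points in bone marrow and ± 0.450 in v-Abl cells.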

Other observations

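Of the tests in this part, those of copying between JH segments, the sequencing run, the frame call and the Ighv5-2 sequence were chosen only after the result was seen.

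CBE2mut and CBE2inv libraries held more junctions of JH4 with other JH segments than WT. Copying between similar JH sequences during PCR was argued against, since 59.3% of these reads in the 6 CBE2 libraries carried a run of at least 8 bases of a D segment between both JH segments, where under 10% was set as the mark of copying. Reads copied many times were argued against too, since the log2 difference of the JH zone between CBE2mut and WT was 1.69 with the same coordinates collapsed, against 1.90, and that of CBE2inv was 1.90 against 2.12. The run stays open, because 0 libraries of another genotype were in the run of the CBE2 libraries, and CBE12mut, in the run of WT, was lower than WT per 100000 junctions (1436 against 1937) but higher per 100 D joins (11.2 against 3.05), as were CBE1mut and CBE1inv with an intact CBE2 (6.16 and 5.04). Genotype and run cannot be told apart for the CBE2 libraries, the rise per 100 D joins in the run of WT is covered by neither that run nor the loss of CBE2 alone, and no effect of CBE2 on these joins was tested.

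In WT bone marrow, Ighv5-2 joins were in frame less often than 1 in 3 (28.6%) and other V joins more often (53.2%). A limit on unaligned bases stays open for Ighv5-2: Ighv2-2, which it would touch alike, lay above it by 3.24 points on average in WT (7.05, 2.33 and 0.346 by library, SD 3.44), but in CBE12mut Ighv2-2 lay below it (22.2% against 26.2%). Copied reads were argued against by 28.8% for Ighv5-2 with identical reads collapsed. A frame call that favours other V segments was argued against for mm9 segments by their 35.1% in untreated WT v-Abl cells, and with Ighv5-1, Ighv2-2 and Ighv5-4 left out as well the shares were 33.4% there and 55.7% in WT bone marrow. In treated WT v-Abl cells, where the farthest part held 4043 junctions per 100000 and the nearest 2888, the latter share was 29.6%. The v-Abl reads had another alignment target, so a frame call that is off on the 129 segments alone is not covered. A property of the Ighv5-2 sequence stays open: in untreated WT v-Abl cells its share was 34.8%, but the lowest of those libraries and the highest WT bone marrow library were both at 30.8%, so selection among bone marrow pro-B cells may be the source but was not shown for Ighv5-2.

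In CBE12mut, joins of Ighd1-1 to JH4 fell more than those of other D segments. Ighd1-1 made up 2.38% of D joins in CBE12mut and 22.1% in WT. Removal of Ighd1-1 joins by later V joining would keep Ighd1-1 inside V joins, but it made up 2.76% of V joins with a readable D against 19.6% in WT. What lowered Ighd1-1 stays open; a loss at the D-to-J step was not tested, and no table here decides it.

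Other splits of the same 6 libraries were fitted for each count of called segments, and 10 splits are too few for a share under 0.05. The real split and the highest of the other splits called 146 and 0 segments for CBE12mut, 101 and 0 for CBE1mut, 16 and 0 for CBE1inv, 20 and 13 for CBE2mut, 8 and 0 for CBE2inv and 72 and 0 for CBE1inv minus CBE1mut. They called 65 and 0 for treatment in WT and 62 and 0 in 3CBEdel, and in each of these 8 comparisons 1 of the 10 splits, the real one, gave as many. For CBE2inv minus CBE2mut the values were 6 and 34, and 3 of the 10 splits gave as many as the real one. A split that calls several times the real count points to a structure of the samples, and leaving out CBE2mut replicate 1 raised the real count to 32. For 3CBEdel minus WT the values were 2 and 2 untreated and 1 and 1 treated, and 2 of the 10 splits gave as many in each. For the difference of treatment effects 100 of 100 splits drawn gave as many as the real count of 0 (highest 2), but every split gives at least 0, so that count decides nothing.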
